A study of Saccharomyces cerevisiae S288C with 12 samples.

How the data were processed

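Chromatin immunoprecipitation of Cse4, the yeast centromeric histone H3 variant, was sequenced from 3 strains of Saccharomyces cerevisiae. Per the labels, all 3 strains lacked Psh1 and carried Cse4 with a 6His-3HA tag under the GAL promoter. The tagged protein was wild type, K215/216A (lysines 215 and 216 replaced by alanine) or K215/216R (the same lysines replaced by arginine). Cells were grown in 2% raffinose at 30 degrees C and given 2% galactose for 2 hours. Chromatin was sonicated to fragments of 100 bp on average, and the tagged protein was taken down with beads carrying an antibody to HA, per the labels. Each strain had 2 immunoprecipitated and 2 input libraries, 12 in all. The 6 immunoprecipitated libraries were analysed here, and the 6 input libraries were not used.

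Per the submitters' processing notes, reads were aligned to the sacCer3 genome with Bowtie 1.0.0, peaks were called with MACS2 2.1.1.20160226, and bedtools 2.25.0 was used. The control used in calling and the filters applied before calling were not stated. With an input as control, the local background of MACS2 follows the input reads, and without one it follows the immunoprecipitated reads themselves, so the meaning of the local background and of the depth measure drawn from it depends on this. The authors called peaks on each library separately. In each deposited list the fold enrichment is a ratio of the pileup at the summit to a local background, as MACS2 writes it. The deposited score is 10 times the −log10 q, without decimals. The deposited −log10 p and −log10 q refer to the summit, and the smallest −log10 q was 1.30 in every library, which is a q of 0.05. The last deposited column is the distance from the peak start to the summit in bases. The authors also deposited 1 merged list per strain, whose regions were found to be the joined overlapping peaks of both libraries, with the mean of the authors' fold values of the joined peaks. The authors' fold values were used to describe and to rank peaks within a library. Means of fold per strain were also set side by side, without a test.

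Genes were taken from the RefSeq annotation of the R64 assembly, which is the sacCer3 build, with 6002 nuclear protein-coding genes and 275 tRNA genes. Strand was read from the systematic gene name. A promoter was the 500 bp upstream of the annotated gene start, and it was called in a library when a summit fell inside it. It was called in a strain when both libraries had a summit there. tRNA genes were called by the same upstream window, which leaves out the gene itself. The promoter windows covered 21.3% of the annotated span of 12.0 Mb. As a background, the summits of each chromosome were shifted together by a random distance around its annotated span, 1000 times per library. Neither a genome sequence nor centromere positions were at hand, so a centromere interval was defined as the space between the innermost genes of the left and right arms, 630 to 2541 bp long on the 16 chromosomes. This replaced the planned overlap with the centromere itself. Centromere cores entered from general knowledge served only as an added alternative.

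Depth was not stated, but MACS2 values allow it to be recovered. The pileup and the local background were solved from the fold and the p of each peak under a Poisson tail. A whole-number pileup was found within 0.001 for 99.6% to 99.8% of peaks per library. The lowest local background of a library was taken as its genome background and as a measure of depth. Pileups were thinned by binomial sampling to the lowest genome background, and peaks were kept by the p threshold of the shortest list. Thinning starts from peaks called at full depth, so it cannot restore peaks that a shallower library missed. Tests on simulated data ran first. The recovery returned 99.9% of 1000 simulated peaks. A ribosomal protein list set to 0.25 of the occupancy of other genes was called in 93.0% of simulations over 6002 genes, and unchanged lists gave calls in 0.13% of tests. In 8000 simulated sites the ratio of sites called at the higher to those called at the lower depth was 1.46 before thinning and 0.99 after it.

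Libraries were grouped by the strain in the labels. Peak number, covered bases, centromere intervals with a peak and promoter share were compared by exact permutation tests of the difference of means, two-sided. The smallest p these can give is 0.33 for 2 libraries against 2 and 0.067 for 4 against 2. Similarity between libraries was the Jaccard index of covered bases for 15 pairs, tested one-sided against the other ways of pairing 6 libraries, with a smallest p of 0.067. Gene lists were tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 54 tests (18 lists in 3 strains) and a threshold of 0.05. There were 16 fixed lists drawn from general knowledge, a list of genes within 20 kb of a chromosome end, and a list of tRNA genes. The fixed lists were earlier Cse4 sites, galactose regulon, glycolysis and fermentation, ribosomal proteins, histones, stress chaperones, respiration, amino acid biosynthesis, phosphate, kinetochore, cohesin and condensin, pheromone response, cell wall, sugar transport, meiosis and ribosome biogenesis. Intervals for shares are Wilson 95% intervals and cover counting error only.

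The tests, the lists and the rule for named genes were set before the data were examined. The rule named every centromere, and in each strain the 10 genes with the best mean rank by fold among promoters called in both libraries and over 1 kb from a centromere. It also named the 10 best-ranked genes among promoters called in both libraries of one strain and in neither of another, for each mutant against wild type in each direction. Up to 4 members per strain of a fixed list that passed its test were named, as were all earlier Cse4 sites and GAL1, GAL10 and GAL7. Alternatives set at the same time were a −log10 q of at least 5 or 10, equal list lengths, each library left out, a replicate block, peaks within 200 bp joined, a reciprocal overlap of 50%, other promoter definitions, a wider centromere interval, a background without chromosome ends and calls in at least 1 library. Alternatives added later were thinning, the removal of peaks with a local background over 3 times the genome background, hand-entered centromere cores, and pileup over the genome background. The ranking by pileup over the genome background also left out peaks with such a raised local background. Counts of top-ranked peaks near centromeres, gene context of summits and the local background at single loci were also chosen after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.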

Results

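Cse4 was mapped by immunoprecipitation in 3 strains that overexpress it from the GAL promoter in the absence of Psh1, a ubiquitin ligase for Cse4. The strains carried wild type Cse4, K215/216A or K215/216R, with 2 libraries each. The comparisons ask whether replacing lysines 215 and 216 alters where Cse4 is deposited. Coordinates are sacCer3. Depth, given as the recovered genome background in fragments per base, was 59.5 and 126 in the wild type libraries, 146 and 148 in K215/216A, and 86.2 and 156 in K215/216R. The labels do not say that replicates were separate cultures, so each permutation p between strains measures only the spread between these libraries, which may be technical. Fisher's exact p values are over genes within a strain, and genes are not independent replicates.

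Cse4 was called at 3123 to 4822 sites per library, and the number of sites did not separate the strains. Wild type had 3123 and 4720 peaks in replicates 1 and 2, K215/216A had 4575 and 4725, and K215/216R had 3604 and 4822. The means were 3921.5 ± 1129 (SD, n = 2), 4650 ± 106 and 4213 ± 861. K215/216A exceeded wild type by 728.5 peaks (exact permutation p 0.667) and K215/216R exceeded it by 291.5 (exact permutation p 0.667). K215/216R minus K215/216A was −437 (exact permutation p 1), and both mutants together exceeded wild type by 510 (exact permutation p 0.6). Without wild type replicate 1 the difference between K215/216A and wild type was −70.

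Peaks covered 1315 ± 452 kb in wild type, 1641 ± 37.5 kb in K215/216A and 1437 ± 437 kb in K215/216R (SD, n = 2). The median peak was 250 to 280 bp long and the authors' median fold was 1.43 to 1.66 per library. K215/216A exceeded wild type by 326 kb and K215/216R exceeded it by 123 kb (exact permutation p 0.667 for each). K215/216R minus K215/216A was −204 kb (exact permutation p 1), and both mutants exceeded wild type by 224 kb (exact permutation p 0.6). These differences were within the spread between replicates of wild type and of K215/216R. Without wild type replicate 1, K215/216A exceeded wild type by 6.71 kb, and without wild type replicate 2 by 646 kb.

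Peak number followed the genome background over the 6 libraries, with Pearson's r 0.969 (exact permutation p 0.00972, adjusted 0.0292 over 3 relations) and Spearman's rho 0.943 (exact permutation p 0.0167, adjusted 0.05). Without wild type replicate 1 and K215/216R replicate 1, the libraries farthest from the median depth, r was 0.241 over 4 libraries, so the relation rests on those samples. The number of centromere intervals with a peak gave r 0.798 (exact permutation p 0.05, adjusted 0.075) and rho 0.647 (exact permutation p 0.189, adjusted 0.283), with r 0.659 without those libraries. The promoter share gave r 0.277 (exact permutation p 0.572, adjusted 0.572) and rho −0.0857 (exact permutation p 0.919, adjusted 0.919), with r 0.229 without them.

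After thinning to the lowest genome background the libraries held 3123 and 3636 peaks in wild type, 3289 and 3468 in K215/216A, and 3224 and 3575 in K215/216R. The thinned means were 3379.5 ± 363, 3378.5 ± 127 and 3399.5 ± 248 (SD, n = 2).

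**Figure D1:**
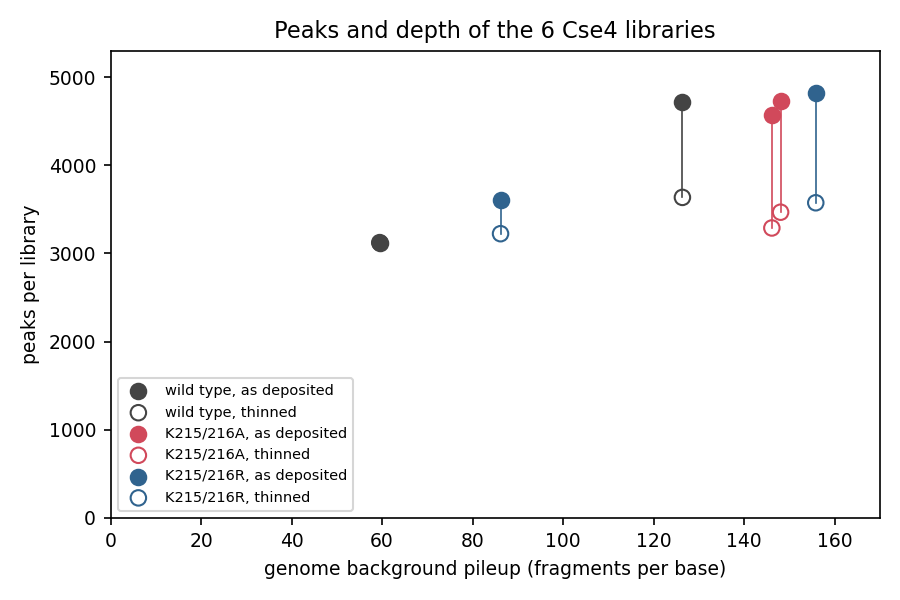
Peaks per library (vertical axis) against the genome background pileup in fragments per base (horizontal axis), as deposited (filled) and after thinning to the lowest genome background (open), with a line joining the values of a library. The open symbol of wild type replicate 1 lies under its filled one at 3123, and the thinned lists lie between 3123 and 3636.

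In every library, peaks lay in intervals between genes that hold the centromeres, the normal sites of Cse4. More of these intervals held a peak in the mutants than in wild type. Peaks covered 995 kb in wild type replicate 1 and up to 1746 kb, in K215/216R replicate 2, so some intervals would hold one by chance. Other intervals between genes were not counted as a background, so these counts do not show an excess of peaks at centromeres. Of 16 centromere intervals, 11 and 14 held a peak in the wild type libraries, 16 and 16 in K215/216A, and 15 and 15 in K215/216R. The interval on chromosome VII (496503 to 497132) held a peak in K215/216A only, and that on VI (148460 to 149109) in both mutants and in neither wild type library. The intervals on II, IX and XII held a peak in 1 of the 2 wild type libraries and in all mutant libraries. K215/216A exceeded wild type by 3.5 intervals and K215/216R exceeded it by 2.5 (exact permutation p 0.33 for each, the smallest possible). Both mutants exceeded wild type by 3.0 intervals (exact permutation p 0.067, the smallest possible). The mutants' excess over wild type replicate 2 alone was 1.5 intervals. Thinning to the lowest genome background left the counts at 11, 14, 16, 16, 15 and 15. When peaks within 500 bp of an interval also counted, the strain means were 15.5 in wild type and 16 in each mutant, and both mutants exceeded wild type by 0.5 (exact permutation p 0.33). Hand-entered centromere cores were overlapped by 0 peaks in the wild type and K215/216R libraries, and 3 of 16 were overlapped in each K215/216A library.

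Among intervals with a peak in every library, the authors' fold at the best peak in the interval differed most on chromosomes IV and VIII. On IV (449277 to 450219) it was 2.36 ± 0.59 in wild type, 4.11 ± 0.47 in K215/216A and 3.09 ± 0.23 in K215/216R (SD, n = 2). On VIII (105092 to 106054) it was 1.94 ± 0.05, 3.62 ± 0.14 and 2.57 ± 0.19. On III (114025 to 115684) it was 1.69 ± 0.26, 2.98 ± 0.03 and 2.26 ± 0.17, and on XIII (267801 to 269018) it was 1.47 ± 0.23, 2.45 ± 0.09 and 1.93 ± 0.23. On IX (355482 to 356142), with a peak in 1 wild type library, it was 3.64 ± 0.40 in K215/216A and 2.58 ± 0.49 in K215/216R. On V the 3 strains had 2.30 ± 0.29, 2.33 ± 0.13 and 2.34 ± 0.11, and on XVI they had 2.03 ± 0.14, 2.09 ± 0.10 and 1.96 ± 0.12. The other intervals with a peak in every library were those on I, X, XI, XIV and XV, where strain means were 1.74 to 2.46 in wild type, 2.48 to 2.73 in K215/216A and 2.13 to 2.75 in K215/216R. Fold was not tested between strains.

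**Figure D2:**
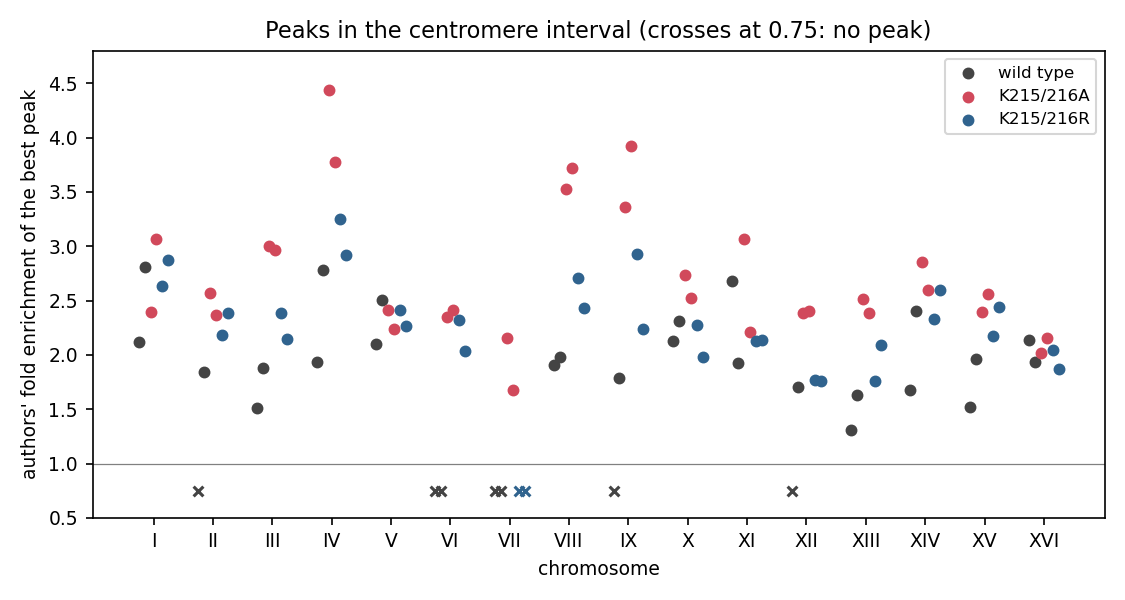
The authors' fold enrichment of the best peak in each centromere interval (vertical axis) by chromosome (horizontal axis), 1 point per library, with crosses for intervals without a peak. Crosses lie on II, VI, VII, IX and XII, 7 of them in wild type libraries and 2 in K215/216R libraries.

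Among the 100 peaks with the highest fold in each library, those within 1 kb of a centromere interval numbered 1 and 5 in wild type, 19 and 15 in K215/216A, and 7 and 6 in K215/216R. The means were 3.0 ± 2.83, 17.0 ± 2.83 and 6.5 ± 0.71 (SD, n = 2). K215/216A exceeded wild type by 14 and K215/216R exceeded it by 3.5 (exact permutation p 0.33 for each, the smallest possible). K215/216R minus K215/216A was −10.5 (exact permutation p 0.33), and both mutants exceeded wild type by 8.75 (exact permutation p 0.133). After thinning K215/216R exceeded wild type by 3.5 (exact permutation p 0.667). Of the same 100 peaks, those within 10 kb exceeded wild type by 12 in K215/216A and 1.0 in K215/216R. Those within 50 kb exceeded it by 8.5 and 1.0. Within 50 kb of an interval lay 18.3% ± 0.20 of all wild type peaks, 18.6% ± 0.39 of those of K215/216A and 19.3% ± 0.62 of those of K215/216R.

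**Figure D3:**
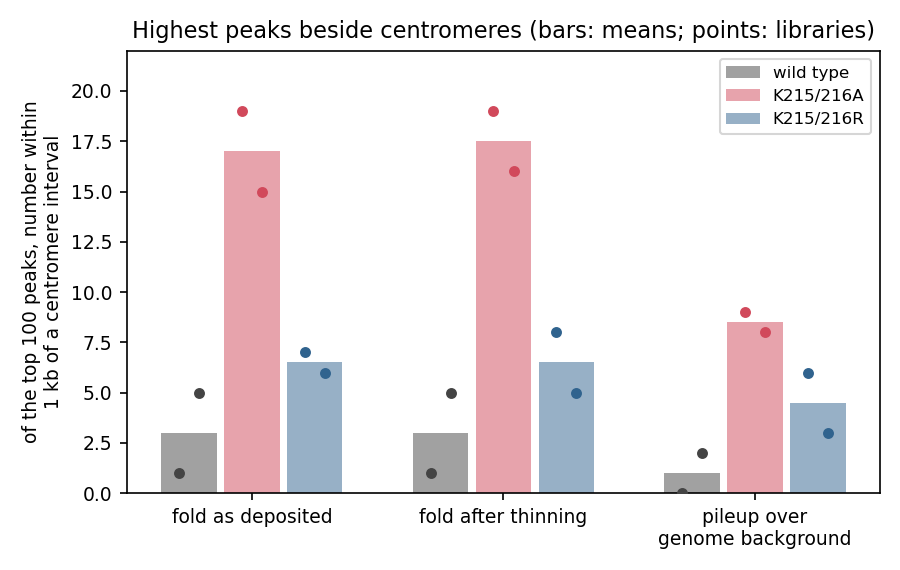
Number of the 100 highest peaks of each library that lie within 1 kb of a centromere interval (vertical axis), ranked by fold as deposited, by fold after thinning and by pileup over the genome background. Bars are means of 2 libraries and points are libraries, and the K215/216A points lie at 19 and 15 as deposited and at 9 and 8 by pileup over the genome background.

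Summits lay in promoters more often than shifted placement gave, in all 3 strains, and most often in K215/216A. The promoter share was 32.1% ± 0.40 in wild type, 36.4% ± 0.01 in K215/216A and 32.8% ± 1.84 in K215/216R (SD, n = 2). Shifted summits had a median share of 21.3% to 21.4% per library and reached at most 23.8% in 1000 shifts. The shifts place summits evenly along a chromosome, and no input or untagged library was set beside them. The excess in promoters is therefore not shown to be particular to Cse4. Per library the Wilson 95% intervals were 30.8% to 34.1% and 30.5% to 33.2% in wild type, 35.0% to 37.8% in each of the K215/216A libraries, and 32.6% to 35.7% and 30.2% to 32.8% in K215/216R. K215/216A exceeded wild type by 4.26 percentage points (exact permutation p 0.33, the smallest possible), more than the spread between replicates. K215/216R exceeded wild type by 0.70 points (exact permutation p 1), less than its own spread. K215/216R minus K215/216A was −3.56 points (exact permutation p 0.33), and both mutants exceeded wild type by 2.48 (exact permutation p 0.267). After thinning the shares were 32.9% ± 0.70, 38.4% ± 0.37 and 33.8% ± 0.70.

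Summits between divergent genes made up 13.0% ± 0.19 in wild type, 15.1% ± 0.18 in K215/216A and 13.1% ± 0.41 in K215/216R, against 9.04% of the annotated span. Summits between tandem genes made up 21.2% ± 0.40, 23.1% ± 0.10 and 22.2% ± 1.83, against 13.3% of the span. Summits between convergent genes made up 5.42% ± 0.42, 5.64% ± 0.74 and 6.17% ± 0.26, against 3.98%. Genes held 59.9% ± 0.09, 55.8% ± 0.47 and 58.1% ± 2.57 of summits, against 73.7% of the span.

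Similarity of the peak lists was compared within and between strains. The Jaccard index of covered bases averaged 0.528 within strains and 0.496 between strains (exact permutation p 0.133, one-sided, over 15 pairings, with a smallest possible p of 0.067). The difference of 0.032 was 0.0456 at equal list length and 0.0396 after thinning, and it was −0.00793 without K215/216A replicate 1 and −0.000335 without K215/216A replicate 2. The highest value joined wild type replicate 2 with K215/216R replicate 2, at 0.603, and the K215/216A libraries had 0.590. The wild type libraries had 0.465 and the K215/216R libraries 0.528. The lowest value joined wild type replicate 1 with K215/216A replicate 1, at 0.387.

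Of 6002 protein-coding genes, 903 (15.04%) had a promoter summit in both wild type libraries, 1429 (23.8%) in both K215/216A libraries and 1058 (17.6%) in both K215/216R libraries. After thinning to the lowest genome background the numbers were 797 (13.3%), 982 (16.4%) and 853 (14.2%). Single libraries as deposited had 1143 and 1701 such promoters in wild type, 1872 and 1952 in K215/216A, and 1383 and 1705 in K215/216R. As deposited, a core of 570 promoters (9.50%) was called in both libraries of all 3 strains. The best-ranked promoters away from centromeres overlapped between strains. TOS6, GAL1 and SNF11 were among the 10 best of each strain, and GAT1 was among the 10 best of wild type and K215/216R. GAL10 shares the summit and the rank of GAL1 in every strain, and in K215/216A only the limit of 10 names left it out.

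The promoter of TOS6 (YNL300W, chromosome XIV, gene 65744 to 66052) had an authors' fold of 3.38 ± 0.43 in wild type, 2.71 ± 0.06 in K215/216A and 3.32 ± 0.25 in K215/216R (SD, n = 2). The promoter of SNF11 (IV, 592439 to 592948) had 3.0 ± 0.35, 3.22 ± 0.01 and 3.11 ± 0.30. GAT1 (VI, 95966 to 97498) had 3.36 ± 0.49, 2.14 ± 0.13 and 3.23 ± 0.27. PHO4 (VI, 225020 to 225958), which shares its summit with YFR035W-A, had 2.13 ± 0.05, 2.77 ± 0.06 and 2.02 ± 0.06. THI2 (II, 700490 to 701842) had 2.87 ± 0.17, 1.68 ± 0.29 and 2.45 ± 0.24. CMC4 (XIII, 652594 to 652887) had 1.91 ± 0.13, 2.81 ± 0.01 and 2.65 ± 0.13. GAL1 (II, 279021 to 280607) and GAL10 (II, 276253 to 278352) share a summit, with folds of 3.14 ± 0.54, 2.57 ± 0.05 and 3.14 ± 0.19, in a region whose local background was 3.47 to 6.22 times the genome background.

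The others among the 10 best in wild type were ARG8, OLE1, COT1 and COA6, with mean folds of 2.81 to 2.99. In K215/216A they were SFC1, OM14, ERG11 and HOG1, with mean folds of 2.76 to 2.85. In K215/216R they were PUT4, OXA1, MIS1 and the pair PHM7 and YOL085C with a shared summit. Their mean folds were 2.88 to 3.06. All of these were called in both libraries of all strains, except COT1, which was called in 1 K215/216R library.

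More promoters were called in K215/216A and not in wild type than the other way round. There were 294 called in both K215/216A libraries and in neither wild type library, and 70 in both wild type and neither K215/216A library. The other pairings of the same 4 libraries gave 26, 120, 39 and 114. Of the 294, a peak still overlapped the promoter window in a wild type library for 74 and none did for 220, and 152 stayed strain-specific after thinning. The imbalance was smaller after thinning, with 186 in K215/216A and not wild type and 98 the other way round, and at equal list length, with 194 and 96. Leaving out 1 of these libraries loosens the rule, so the count can only rise, and it reached 657 without wild type replicate 2. The best-ranked were ERG4, TVS1, YPR063C, YPR064W, YML100W-A, TSA1, ECM3, VMA5, VPS8 and IZH1. In 8 of these 10 a wild type peak overlapped the window with its summit elsewhere, the exceptions being TSA1 and IZH1. YPR063C and YPR064W share a summit, so the 10 genes are not 10 separate sites. TSA1 (XIII, 220138 to 220728) had a fold of 2.00 ± 0.02 in K215/216A (SD, n = 2). IZH1 (IV, 1434924 to 1435874) had 1.92 ± 0.14 in K215/216A and 2.06 ± 0.26 in K215/216R.

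The best-ranked promoters of wild type not called in K215/216A were CSR1, YSP3, MCD1, PCT1, YCH1, TOG1, LYS4, JLP1, COA1 and UBP7. Their mean folds were 1.95 to 2.50. PCT1 and YCH1 share a summit, as do COA1 and UBP7. A K215/216A peak overlapped the window in 9 of the 10, the exception being JLP1 (XII, 25756 to 26994; fold 1.97 ± 0.13 in wild type and 1.62 ± 0.07 in K215/216R). Over all 70, a K215/216A peak overlapped 38.

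Between K215/216R and wild type the numbers of strain-specific promoters lay within the range of other pairings. There were 79 called in K215/216R and not in wild type and 67 the other way round, and other pairings of these libraries gave 50, 214, 48 and 81. A peak overlapped the window in the other strain for 35 of the 79 and 37 of the 67. Leaving out 1 library, which can only raise these counts, gave as many as 354, without wild type replicate 2, and 295, without wild type replicate 1. The best-ranked in K215/216R were UBX6, IZH1, BAT2, YOR343C, PFA4, YBL005W-A, YBL005W-B, GSC2, SIR2 and ETT1. No wild type peak overlapped IZH1, BAT2, YBL005W-A, YBL005W-B, SIR2 or ETT1. YBL005W-A and YBL005W-B have the same window and summit. BAT2 (X, 705744 to 706874) had a fold of 1.90 ± 0.06 in K215/216R and 1.48 ± 0.14 in K215/216A, and SIR2 (IV, 376757 to 378445) had 1.78 ± 0.06 in K215/216R and was called in 1 K215/216A library. The best-ranked in wild type were YSP3, SSL1, THI73, RRN7, PCT1, YCH1, TOG1, LYS4, COQ2 and MVD1. A K215/216R peak overlapped all of these windows except that of COQ2. SSL1 and THI73 share a summit, as do PCT1 and YCH1.

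Between the mutants, 225 promoters were called in K215/216A and not in K215/216R, and 57 the other way round, against 46, 104, 94 and 70 in other pairings. A peak overlapped the window in the other strain for 70 of the 225 and 28 of the 57. Of the 225, 109 stayed strain-specific after thinning, and the thinned numbers were 160 and 87. At equal list length they were 160 and 80. Leaving out K215/216R replicate 2 raised the 225 to 498, and leaving out K215/216R replicate 1 raised the 57 to 233. Such a rise follows from the looser rule.

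Cse4 was rarely called at ribosomal protein promoters. Of 138 such genes, 3 (2.17%) were called in wild type, 8 (5.80%) in K215/216A and 4 (2.90%) in K215/216R, against 15.3%, 24.2% and 17.97% of other genes. Fisher's exact test gave adjusted p of 1e-05, 1.19e-06 and 2.14e-06. At a −log10 q of at least 10 the test passed in both mutants and not in wild type. No input or untagged library was set beside these calls, and the control used in calling was not stated. Fewer calls at these promoters therefore need not mean less Cse4. The called members were led by RPS9A in all 3 strains, with folds of 1.84 ± 0.15, 2.30 ± 0.08 and 2.00 ± 0.13. RPS0A and RPS3 were called in wild type, RPL43B and RPL15B in both mutants, RPL24A in K215/216A and RPL14B in both mutants.

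Genes within 20 kb of chromosome ends were also called less often. The filters before calling were not stated, and how well reads align near chromosome ends was not examined. Fewer calls there therefore need not mean less Cse4. In K215/216A 28 of 257 were called (10.9% against 24.4% of other genes, Fisher's exact test, adjusted p 2.14e-06) and in K215/216R 19 of 257 (7.39% against 18.1%, adjusted p 2.36e-05). In wild type 24 of 257 were called (9.34% against 15.3%, adjusted p 0.066), and the difference between strains was not tested. With promoters of 250 bp none of the strains passed, at a −log10 q of at least 10 K215/216R did not pass, and wild type passed in 5 of 12 alternatives. For tRNA genes a call meant a summit in the 500 bp upstream, with the gene itself left out. tRNA genes were so called for 26 of 275 in wild type, 63 in K215/216A and 55 in K215/216R (9.45%, 22.9% and 20%, adjusted p 0.0699, 1 and 0.816, against protein-coding genes at 15.04%, 23.8% and 17.6%), and in wild type they passed below protein-coding genes in 3 of 13 alternatives. Of the 54 tests, 5 passed the threshold below other genes and none passed above them, while at an unadjusted p under 0.05 there were 7 below and 3 above.

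The 3 above other genes were respiration in K215/216A (18 of 46, 39.1% against 23.7%, Fisher's exact p 0.0223, adjusted 0.15), amino acid biosynthesis in K215/216A (19 of 52, 36.5% against 23.7%, p 0.0478, adjusted 0.258) and phosphate genes in K215/216R (6 of 15, 40.0% against 17.6%, p 0.0351, adjusted 0.21). Respiration genes were called for 6 in wild type and 8 in K215/216R, amino acid biosynthesis genes for 12 and 14, and phosphate genes for 5 in wild type and 7 in K215/216A.

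Counts in the order wild type, K215/216A and K215/216R were 2, 3 and 2 of 11 galactose regulon genes, 0, 4 and 1 of 19 glycolysis and fermentation genes, and 0, 2 and 0 of 11 histone genes. They were 3, 6 and 3 of 24 stress chaperones, 7, 9 and 9 of 45 kinetochore genes, and 2, 4 and 2 of 14 cohesin and condensin genes. Pheromone response genes gave 4, 5 and 3 of 21, cell wall genes 3, 5 and 4 of 31, and sugar transport genes 3, 5 and 2 of 21. Meiosis genes gave 2, 6 and 2 of 32, and ribosome biogenesis genes 3, 6 and 6 of 50. The smallest adjusted p among these lists was 0.268.

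**Figure D4:**
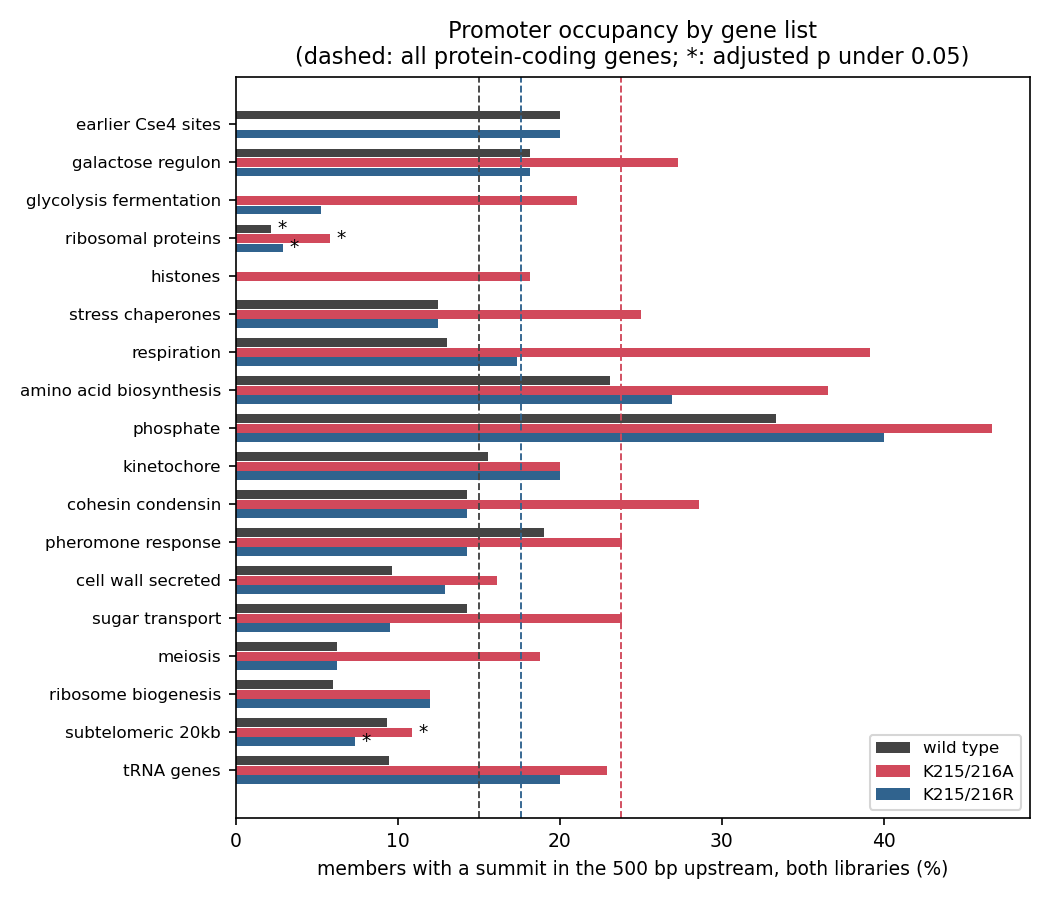
Percent of the members of each gene list with a promoter summit in both libraries (horizontal axis) for the 18 lists (vertical axis) and 3 strains, with dashed lines at the percent of all protein-coding genes. Asterisks mark the 5 tests with an adjusted p under 0.05, ribosomal protein genes in 3 strains and genes within 20 kb of chromosome ends in both mutants.

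Promoters where overexpressed Cse4 has been measured before were mostly not called, which also held for protein-coding promoters as a whole. Of those, 15.04% were called in wild type, 23.8% in K215/216A and 17.6% in K215/216R. A call needed a summit in the window, and peaks overlapping these windows with a summit elsewhere are not counted here. A missing call is therefore not a missing peak. Of the 5 earlier Cse4 sites, COQ3 (XV, 138107 to 139045) was called in both wild type and both K215/216R libraries (folds 1.5 ± 0.08 and 1.48 ± 0.003) and in neither K215/216A library. RDS1 (III, 310958 to 313456) was called in 1 K215/216A library, and SAP4, SLP1 and GUP2 in none of the 6 libraries. GAL7 (II, 274427 to 275527) was called in both K215/216A libraries and 1 K215/216R library. The strain counts were 1, 0 and 1 of 5 (Fisher's exact test, adjusted p 1 in each).

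The authors' merged lists held 2635 regions in wild type, 3511 in K215/216A and 3052 in K215/216R. Regions overlapping both other lists by at least 1 bp numbered 1879 (71.3%), 1857 (52.9%) and 1850 (60.6%). Regions overlapping neither other list numbered 281 (10.7%), 841 (24.0%) and 316 (10.4%). At a reciprocal overlap of 50% they numbered 529 (20.1%), 1123 (32.0%) and 547 (17.9%). The merged lists have no replicates, so these counts were not tested. Every region held peaks of both libraries, so each list is limited by the shallower library of its strain. That library had a genome background of 59.5 in wild type, 146 in K215/216A and 86.2 in K215/216R. No count at equal depth was made, so the larger number in K215/216A cannot be read as sites particular to it.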

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

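All tests in this part were chosen after the result was seen, except that the bounds for the depth and local background tests of peaks beside centromeres were set before those tests were run.

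Local background was raised at 6 chosen loci, in a quantity that was not itself compared between strains. Peaks with a local background over 3 times the genome background numbered 17 to 30 per library. How many of them lie outside these loci was not counted. The median over libraries was 6.62 times the genome background at URA3 (V, 116042 to 117042), 10.1 at CSE4 (XI, 345806 to 346744), 5.39 in the GAL10-GAL1 intergenic region (II, 278589 to 278994) and 2.70 downstream of CYC1 (X, 526696 to 526929). It was 11.8 in the ribosomal DNA on chromosome XII and 5.27 at the CUP1 array on chromosome VIII, both repeated sequences. Over all peaks the median was 1.25.

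For the raised local background at URA3, CSE4, GAL1-GAL10 and CYC1, occupancy of galactose-induced promoters was weighed against extra copies of these sequences in the strains. At 9 other galactose promoters 6 of 54 calls were positive (GAL7, PCL10 and GAL80). Over all protein-coding promoters 19.0% to 32.5% were called per library. The galactose calls bear on GAL10-GAL1 only, since URA3 and CSE4 were taken as genes and CYC1 by its downstream region. They also count peaks and not local background, so they cannot decide whether promoter occupancy raised it. The lowest local background at the raised loci was 2.15, downstream of CYC1 in K215/216R replicate 2. It lay above 1.65, the highest at the 3 other galactose promoters with a peak, as extra copies from an expression construct would give. Galactose promoters without a peak had no value. Promoters outside this set reached similar values, 2.44 and 2.34 at GAT1 in K215/216A and 2.30 at PUT4 in wild type replicate 1. A value of 2.15 is therefore not particular to these loci. The lowest values at URA3, CSE4 and GAL10-GAL1 were 3.79, 6.09 and 3.47. Extra copies cannot be told apart from immunoprecipitated signal here, because the control used in calling was not stated and, without an input, the local background holds that signal itself. The GAL1, GAL10, URA3 and CSE4 peaks may therefore hold reads from a construct.

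The peak lists differed in length between libraries, the longest being 1.54 times the shortest. The strain as the whole cause is excluded, since the libraries of 1 strain differed by up to 1597 peaks and strain means by at most 728.5. After thinning to the lowest genome background the ratio was 1.16, so library depth may account for most of the difference. An effect of the strain within the remaining spread stays open.

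The highest-fold peaks of K215/216A lay beside centromeres more often than those of wild type. The difference was 14 peaks as deposited and 14.5 (SD 2.5) after thinning. Thinning scales pileup and local background by the same factor and re-ranks only peaks called at full depth. It therefore hardly changes fold and cannot exclude library depth. The deepest library, K215/216R replicate 2 with a genome background of 156, had 6 such peaks. K215/216A had 19 and 15 at 146 and 148, and wild type replicate 2 had 5 at 126. The highest depth was thus not where the count was highest. Ranked by pileup over the genome background, the difference was 7.5 (SD 1.12), with both K215/216A libraries above both wild type libraries. This ranking also left out peaks with a local background over 3 times the genome background, so it makes both changes at once. A lower local background beside centromeres could account for part of the difference. It cannot be told apart from Cse4 density for the rest, because 7.5 passed its preset bound of 7 by less than the spread. The replacement by alanine stays open as a biological explanation. K215/216R, with arginine at the same lysines, had 7 and 6 such peaks by deposited fold, against 1 and 5 in wild type and 19 and 15 in K215/216A. Replacing these lysines was thus not followed by a difference of the same size in both mutants. The exact permutation p for K215/216A against wild type was 0.33, the smallest that 2 libraries per strain allow, and no other test was run.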

How the results depend on the processing

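Thinning, removal of peaks with a raised local background, hand-entered centromere cores, the counts of top-ranked peaks, and the alternatives for tRNA ratios and for promoters called per strain were chosen after the data were seen. Of 349 alternative values that could change, 274 kept their direction and their side of the threshold, or without a test stayed within the spread or 1.5 times the main count, 60 moved beyond that and 15 reversed. Another 49 were fixed by construction. Counts of strain-specific promoters with a library of the pair left out could only rise, and those that rose beyond 1.5 times are among the 60. The exact permutation tests between strains could not pass 0.05, so for those results only the direction counts, and no other test was run on them. Equal list lengths fix the peak number and gave no value for it. At the depth of wild type replicate 1 and K215/216R replicate 1, 59.5 and 86.2 fragments per base, weaker sites may have been missed, which was not tested. The cause was not tested for any change below. Exceptions are alternatives that themselves remove peaks or promoter length, or loosen the rule for a strain-specific promoter.

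After thinning, the difference in peak number was −1 for K215/216A minus wild type and 21 for K215/216R minus K215/216A. Leaving out each library gave −70 to 1527 peaks for K215/216A minus wild type, −507 to 1090 for K215/216R minus wild type, −1046 to 172 for K215/216R minus K215/216A, and −288.5 to 1308.5 for both mutants minus wild type. For covered bases these ranges were 6.71 to 646 kb, −197 to 442 kb, −512 to 105 kb and −95.1 to 544 kb in the same order. The low ends came without wild type replicate 1 in each contrast with wild type, and all were negative except for covered bases in K215/216A minus wild type. K215/216R minus wild type also reversed without K215/216R replicate 2, and K215/216R minus K215/216A without K215/216R replicate 1.

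For centromere intervals with a peak, leaving out a wild type library gave 2 to 5 for K215/216A minus wild type. It gave 1 to 4 for K215/216R minus wild type and 1.5 to 4.5 for both mutants. Within 500 bp of the centromere interval the excess over wild type fell to 0.5 for K215/216A, for K215/216R and for both mutants, and K215/216R minus K215/216A was 0. With hand-entered centromere cores K215/216R minus wild type was 0, since neither strain had a peak on a core, and K215/216A minus wild type was 3. Within 500 bp of hand-entered cores K215/216R minus K215/216A was 0, and each mutant exceeded wild type by 2.5. The promoter share of K215/216R minus wild type was −0.243 points at 250 bp and −0.602 to 2.00 over left-out libraries, and K215/216R minus K215/216A was −4.87 to −2.26. Similarity within minus between strains was −0.00793 to 0.0837, negative without either K215/216A library.

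Promoters called in K215/216A and not wild type numbered 149 at a −log10 q of at least 10, 194 at equal list length, 155 at 250 bp and 186 after thinning, with 294 to 657 over left-out libraries. The low end of each such range is the main count, from libraries outside the pair. With a library of the pair left out these counts can only rise, since a condition of the rule is dropped. The lowest value with a library of the pair left out was 374 here and 125, 126, 316, 123 and 124 in the order below. Wild type and not K215/216A rose to 98 after thinning and 96 at equal list length, and gave 30 at a −log10 q of at least 10, 34 at 250 bp and 70 to 271. Wild type and not K215/216R gave 16, 42 and 67 to 295. K215/216A and not K215/216R gave 92, 121 and 225 to 498. K215/216R and not wild type gave 38, 47 and 79 to 354. K215/216R and not K215/216A gave 26 at 250 bp, 87 after thinning and 57 to 233.

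Lists above other genes numbered 1 at a −log10 q of at least 5 (phosphate, K215/216R), 1 at 10 (amino acid biosynthesis, K215/216A), 3 at 1000 bp, 3 with any overlap, and 0 to 1 over left-out libraries (phosphate, without wild type replicate 2). At 1000 bp these were phosphate in wild type and amino acid biosynthesis in both mutants, and with any overlap phosphate in wild type and K215/216A and amino acid biosynthesis in K215/216A. Lists below numbered 3 at a −log10 q of at least 10 and 3 among genes over 20 kb from chromosome ends. In wild type, tRNA genes passed below in 3 of 13 alternatives (without wild type replicate 2, 250 bp and any overlap, adjusted p 0.0136, 0.0198 and 0.00378) and glycolysis in 1 (without wild type replicate 1). Of the alternatives that could change a strain's list result, ribosomal proteins stayed below in 13 of 13 in each mutant and in 12 of 13 in wild type, the exception being a −log10 q of at least 10. Genes near chromosome ends stayed below in 11 of 12 in K215/216A and 10 of 12 in K215/216R. In wild type, where they did not pass as deposited, they passed in 5 of 12, which were each wild type library left out, 1000 bp, any overlap and calls in at least 1 library. Merged regions met in neither other list numbered 529 in wild type and 547 in K215/216R at a reciprocal overlap of 50%.

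Under a replicate block the difference of 728.5 peaks had an exact permutation p of 0.5 (smallest possible 0.5), and no such test between strains passed 0.05 with or without the block. Replicate 1 minus 2 was −1597, −150 and −1218 peaks in the 3 strains, and nothing in the labels says what equal numbers share, so whether they mark a common day or batch stays open.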

Other observations

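All tests in this part were chosen after the data were seen. tRNA genes were set against protein-coding promoters within each library, as the ratio of the shares with a summit in the 500 bp upstream. The ratio was 0.611 and 0.975 in wild type, 1.17 and 1.02 in K215/216A, and 1.04 and 1.11 in K215/216R. Both mutants exceeded wild type by 0.292 (exact permutation p 0.067, two-sided, the smallest possible). Without wild type replicate 1, the library with the lowest depth, the difference was 0.109, and without wild type replicate 2 it was 0.474.

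The fixed lists were also tested among strain-specific promoters, in 68 Fisher's exact tests, of which none passed after adjustment and 3 had an unadjusted p under 0.05. Respiration genes made up the first, with 8 of 46 called in K215/216A and not in wild type (17.4% against 4.8% of other genes, p 0.00154, adjusted 0.105). These were ATP1, COX13, COX7, COX9, KGD2, LSC1, QCR7 and QCR9, and none of the 46 was called in wild type and not in K215/216A. Over the alternatives the adjusted p ran from 0.0301, with any overlap of the promoter, through 0.0458 at 1000 bp and 0.185 after thinning, to 1 at 250 bp and at equal list length. The others were glycolysis and fermentation (ADH1, ENO1, PDC1 and TDH3, 4 of 19, adjusted p 0.415) and, below other genes, genes within 20 kb of chromosome ends (5 of 257, adjusted p 0.569).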
